A study of Mus musculus with 18 samples.

How the data were processed

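The study measured early gene expression in mouse spinal cord-derived astrocyte cultures carrying a retrovirus with Ascl1ERT2, Ngn2ERT2 or DsRed. Per the labels' protocols, cells grew in DMEM/F12 with B27 and serum, received hydroxytamoxifen (OHT, 100 nM) for 24 h where stated, and were sorted before RNA extraction with a PicoPure kit. The aligner, the genome build, the annotation and the counting tool are not given in the sources used here.

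The deposited signal values are gene read counts that the authors divided by a size factor per library, as the values show. In all 18 columns, 100% of the values were whole multiples of a single step, within a tolerance of 0.001, so that whole reads were recovered. The table has 25750 Ensembl mouse genes, of which 118 are 0 in every library. Symbols were taken by gene identifier from GENCODE M21 (GRCm38) for 25584 genes, and 166 had no match. Coordinates in the report come from that annotation. Gene list members without a value in the table numbered 26, among them Tubb3 and Neurod1. A single read was worth 0.445 to 2.03 normalised counts, so that genes near the filter rest on few reads and are imprecise. Pseudogenes took 13.5 to 19.5% of the reads, mitochondrial genes 1.22 to 2.35%, and the 10 most abundant genes 4.74 to 6.88%.

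Samples were grouped by virus and treatment from the titles and tags, which were the same for 17 libraries. The remaining library (titled DsRed without OHT, tagged with OHT) was left out of all comparisons. No sample was dropped for quality. The comparisons, tests, filters, gene lists, naming rule and other settings to try were chosen before the data were examined.

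Gene tests used limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3 on log2(normalised count + 1). A single model held the 6 groups and 17 libraries, with 11 residual degrees of freedom and a median of 5.98 prior degrees of freedom. Genes with a value of at least 10 in at least 2 libraries were tested (15293), and p-values were 2-sided and adjusted by Benjamini-Hochberg within a comparison, with 0.05 as the threshold. A gene is said to be called when its adjusted p is under 0.05. There were 11 comparisons: 8 of groups and 3 interaction terms between virus and OHT. Normalised values are not raw counts, so edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads served as alternatives. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures. Fold changes are log2 with SE from limma, and group values are means of normalised counts with SD. With few reads in the lower group, ratios are those of the means, with exact 95% intervals for the counts.

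The naming rule took, for each of the 3 main comparisons with OHT, the 10 highest and 10 lowest fold changes among called genes, and 5 of each for the others. A gene also needed an absolute log2 fold change of at least 1, a mean of at least 20 in the higher group, no overlap between the groups and a symbol that is not provisional. Ascl1, Neurog2, Esr1, Neurod4, Insm1, Hes6, Dll1, Dll3, Dcx, Tubb3, Gfap, Sox9, Olig2 and Mki67 were always named, and up to 4 members of each list with the smallest p. The text gives up to 2 of these, for lists with at least 3 called members in most cases, limits that were set after the results were seen.

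The 25 gene lists were tested with limma's camera at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, and adjusted by Benjamini-Hochberg over the lists of a comparison. Camera asks whether members rank above or below other genes. Fry asks whether members changed at all in a shared direction, whatever other genes did. Called members were counted with adjustment over all genes and adjusted over the list alone. The lists cover the Notch pathway, neurogenic transcription factors, neuronal cytoskeleton, adhesion and synapse, inhibitory, excitatory and spinal V2 neurons, astrocytes, the oligodendrocyte lineage, microglia, fibroblasts with pericytes and smooth muscle, endothelial, ependymal and Schwann cells, S phase, G2 and mitosis, cell cycle inhibitors, cholesterol synthesis, oestrogen receptor targets, the unfolded protein response, oxidative stress, interferon response, immediate early genes, BMP and Id genes, mitochondrially encoded RNAs and RNA quality. Some genes stand in more than 1 list.

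The pipeline was tested on simulated data with 200 changed genes among 14956 to 15293 and the group sizes of each comparison. With limma it recovered 83% of 4-fold and 49% of 2-fold changes at the sizes of Ascl1ERT2 against DsRed with OHT (5 unchanged genes called), 87 and 55% for Ngn2ERT2 against DsRed (3), and 94 and 53% between the factors (14). For OHT against none it recovered 86 and 46% in Ascl1ERT2 (2), 84 and 37% in Ngn2ERT2 (9) and 81 and 33% in DsRed cells (7). Without OHT it recovered 76 and 25% for Ascl1ERT2 (8) and 80 and 29% for Ngn2ERT2 against DsRed (8).

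The alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, median-ratio and quantile rescaling, limma without trend and robust, only the compared groups in the model, the replicate number as a block, the conflicting library placed by its title or tag, edgeR, DESeq2 and leaving out each library. Leaving out 3 libraries together was added after the data were seen. Where 1 library of a group remained, it was assumed to vary like the other groups.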

Results

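RNA was sequenced from mouse spinal cord-derived astrocyte cultures that had been transduced with a retrovirus encoding Ascl1ERT2, Ngn2ERT2 or DsRed. Ascl1 and Neurog2 (Ngn2) are basic helix-loop-helix transcription factors that drive neurogenesis. Each was fused to a hormone-binding part of an oestrogen receptor, so that 4-hydroxytamoxifen (OHT) should activate it. DsRed, a red fluorescent protein, was the control. Cells received 100 nM OHT for 24 h or none, and the transduced cells were collected by fluorescence-activated cell sorting. The 18 libraries comprised Ascl1ERT2 with OHT (n = 4) and without (n = 2), Ngn2ERT2 with OHT (n = 4) and without (n = 2), and DsRed with OHT (n = 3) and without (n = 2). The remaining library, of DsRed cells, had a title and a treatment tag that disagreed on OHT, and it entered no comparison. Libraries are named here by group and by the number in their titles.

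The table gave normalised read counts for 25750 genes, from which whole reads could be recovered. Ascl1ERT2 OHT 2 to 5 held 6155889, 4085409, 4369571 and 3862512 reads in genes, and Ascl1ERT2 no OHT 1 and 3 held 7708172 and 4813880. Ngn2ERT2 OHT 1 to 4 held 3535209, 3545613, 4287261 and 3745890, and Ngn2ERT2 no OHT 2 and 3 held 5791135 and 3617193. DsRed OHT 2 to 4 held 10149542, 5221409 and 4034871, DsRed no OHT 1 and 3 held 2211465 and 6042130, and the unassigned library held 4885684. Nothing states that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

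Ascl1 (ENSMUSG00000020052, chromosome 10, 87490819 to 87493660, minus strand) had a normalised count of 237 ± 28.6 (SD, n = 4) in Ascl1ERT2 cells with OHT and 63.6 ± 20.4 (SD, n = 3) in DsRed cells with OHT. Without OHT it had 178.5 ± 35.1 in Ascl1ERT2 and 186 ± 52.3 in Ngn2ERT2 cells (SD, n = 2 each), so it does not part these labels. Neurog2 (ENSMUSG00000027967, chromosome 3, 127633135 to 127635631, plus strand) lay between 29.0 and 53.1 in the 6 Ngn2ERT2 libraries and between 0 and 3.85 in the other assigned libraries. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, plus strand), the oestrogen receptor gene, lay between 9.10 and 34.5 in DsRed cells, between 45.0 and 139.8 in Ascl1ERT2 cells and between 117.5 and 278 in Ngn2ERT2 cells. Reads from the viruses may be counted at these genes, so their values do not measure the cells' own transcripts.

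**Figure D1:**
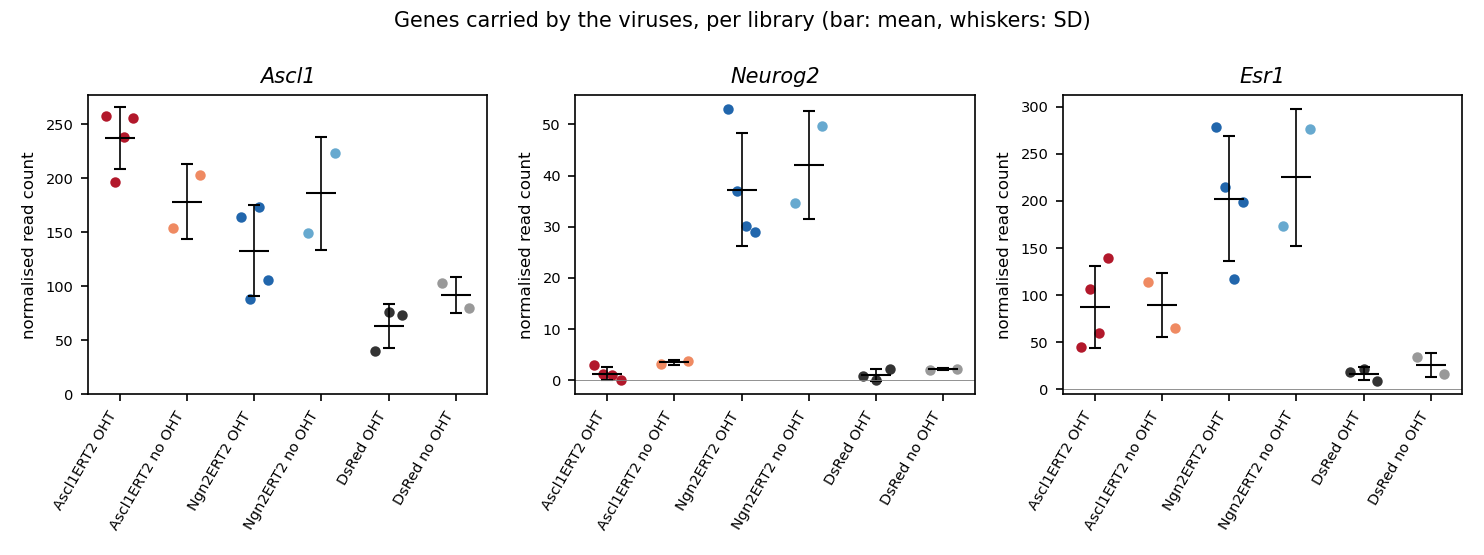
Normalised read counts of Ascl1, Neurog2 and Esr1 (vertical axes) in each library, by group (horizontal axis), with a point per library, a bar at the mean and whiskers of 1 SD. Neurog2 reached 29.0 to 53.1 in the 6 Ngn2ERT2 libraries and at most 3.85 in the others.

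Sox10, a transcription factor of the oligodendrocyte lineage, had 34.7 normalised counts in Ascl1ERT2 OHT 3, 46.1 in Ngn2ERT2 OHT 2 and 40.9 in DsRed OHT 4, and at most 3.55 in any other library. Mbp, which encodes myelin basic protein, had 75.1, 302 and 303 in the same 3 libraries. Aif1, a microglial marker, had 128 in DsRed OHT 4, 48.5 in Ascl1ERT2 OHT 3 and 14.5 in Ngn2ERT2 OHT 2, with at most 22.3 elsewhere. Of the myelin gene Plp1, Ascl1ERT2 OHT 3 held 65.8, less than Ascl1ERT2 OHT 4 (89.1), and the others held 173 and 168.

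**Figure D2:**
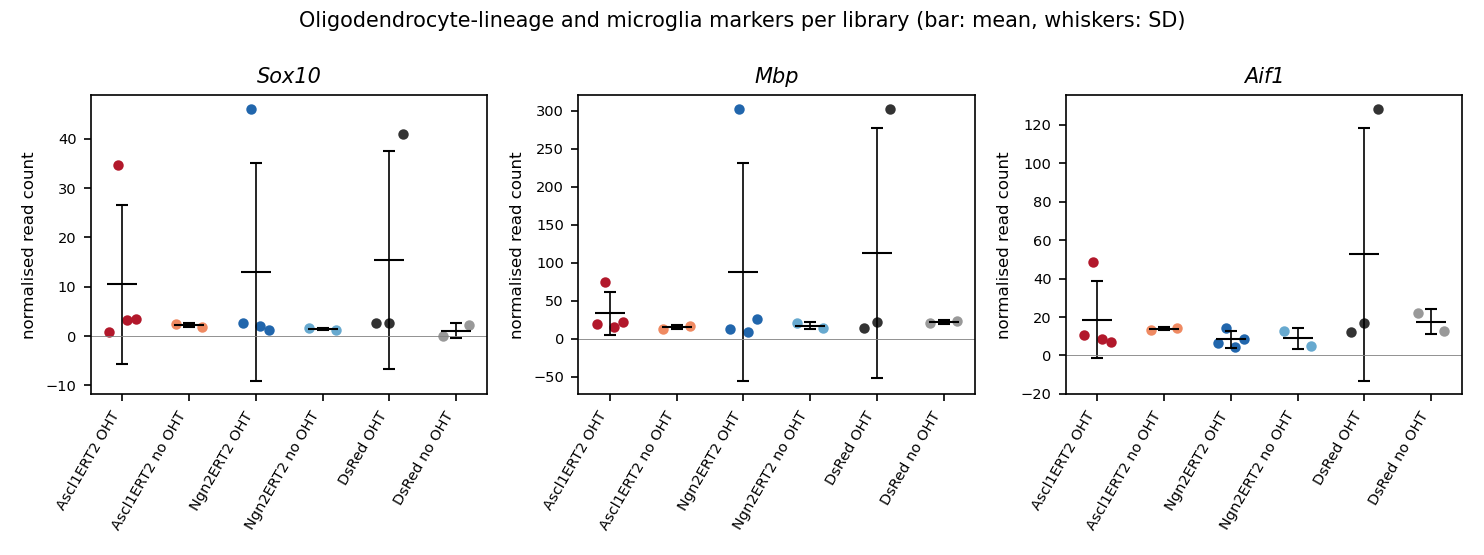
Normalised read counts of Sox10, Mbp and Aif1 (vertical axes) in each library, by group (horizontal axis), with a point per library, a bar at the mean and whiskers of 1 SD. Sox10 stood at 34.7, 46.1 and 40.9 in Ascl1ERT2 OHT 3, Ngn2ERT2 OHT 2 and DsRed OHT 4.

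With OHT, 17 of 23 tested neurogenic transcription factors rose in Ascl1ERT2 cells relative to DsRed cells and none fell. Of the ependymal genes, which serve motile cilia, 8 of 10 fell. Of the cholesterol synthesis genes 11 of 22 fell (5 without DsRed OHT 2), but 0 with OHT against none in Ascl1ERT2 cells. Of the astrocyte genes 13 of 35 fell and 1 rose. These lists were fixed beforehand, and their camera calls were lost with an estimated correlation (adjusted p = 0.0571, 0.0571, 0.367 and 0.415). Among 15293 genes tested with limma, 1091 were higher and 1179 lower in Ascl1ERT2 cells (n = 4) than in DsRed cells (n = 3) at a Benjamini-Hochberg adjusted p under 0.05. Of these, 564 and 578 differed by at least 2-fold, on the scale of log2(normalised count + 1). The count fell to 1448 without DsRed OHT 2.

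Among the genes that met the naming rule, the highest fold changes were those of Krt5, a keratin of basal epithelia, Cbfa2t3, a transcriptional corepressor, and Shisa2. Their log2 fold changes were 4.84 ± 0.66, adjusted p = 1.24e-04 for Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand), 4.48 ± 0.28, adjusted p = 5.48e-08 for Cbfa2t3 (ENSMUSG00000006362, chromosome 8, 122625141 to 122699109, minus strand) and 4.38 ± 0.53, adjusted p = 4.32e-05 for Shisa2 (± SE). Cbfa2t3 had a normalised count of 231 ± 72.5 in Ascl1ERT2 cells (SD, n = 4) and 9.21 ± 2.33 in DsRed cells (SD, n = 3). Rbfox3, the splicing factor known as NeuN, reached 4.38 ± 0.48, the Notch ligand Dll1 3.96 ± 0.47, and Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, 3.85 ± 0.37, from 133 ± 25.1 to 2122 ± 1116 counts. Also among the 10 highest were the bombesin-family receptor Grpr (4.21 ± 0.62), the synaptic scaffold Homer2 (4.15 ± 0.32), the calcium sensor Doc2b (3.93 ± 0.62) and the protein kinase A inhibitor Pkib (3.81 ± 0.30). Krt5 and Grpr had 3 and 2 reads in all DsRed OHT libraries together, so that the ratios of their means were 75.0 (95% counting interval 25.7 to 364) and 56.4 (95% counting interval 15.6 to 466), intervals that cover counting error only.

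The 10 lowest fold changes belonged to Ccn2, a matricellular protein (-3.22 ± 0.53, adjusted p = 9.03e-04), Plppr4 (-3.00 ± 0.47), the myosin light chain kinase Mylk (-2.88 ± 0.32) and Fam84b (-2.65 ± 0.29). They also included Fam181a (-2.54 ± 0.55), the kinase Nek5 (-2.51 ± 0.38), the natriuretic peptide receptor Npr3 (-2.41 ± 0.71, adjusted p = 0.0302) and the cilia- and flagella-associated genes Cfap52 (-2.75 ± 0.29), Cfap45 (-2.49 ± 0.21) and Cfap161 (-2.42 ± 0.40). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683, plus strand) had 80.7 ± 23.7 counts in Ascl1ERT2 cells and 785 ± 361 in DsRed cells (SD). The call of Npr3 was lost without Ascl1ERT2 OHT 2, 4 or 5 or DsRed OHT 2, 3 or 4 (0.0568 to 0.124), where brackets after a library left out give the adjusted p. Every other gene named so far kept its call without any single library.

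**Figure D3:**
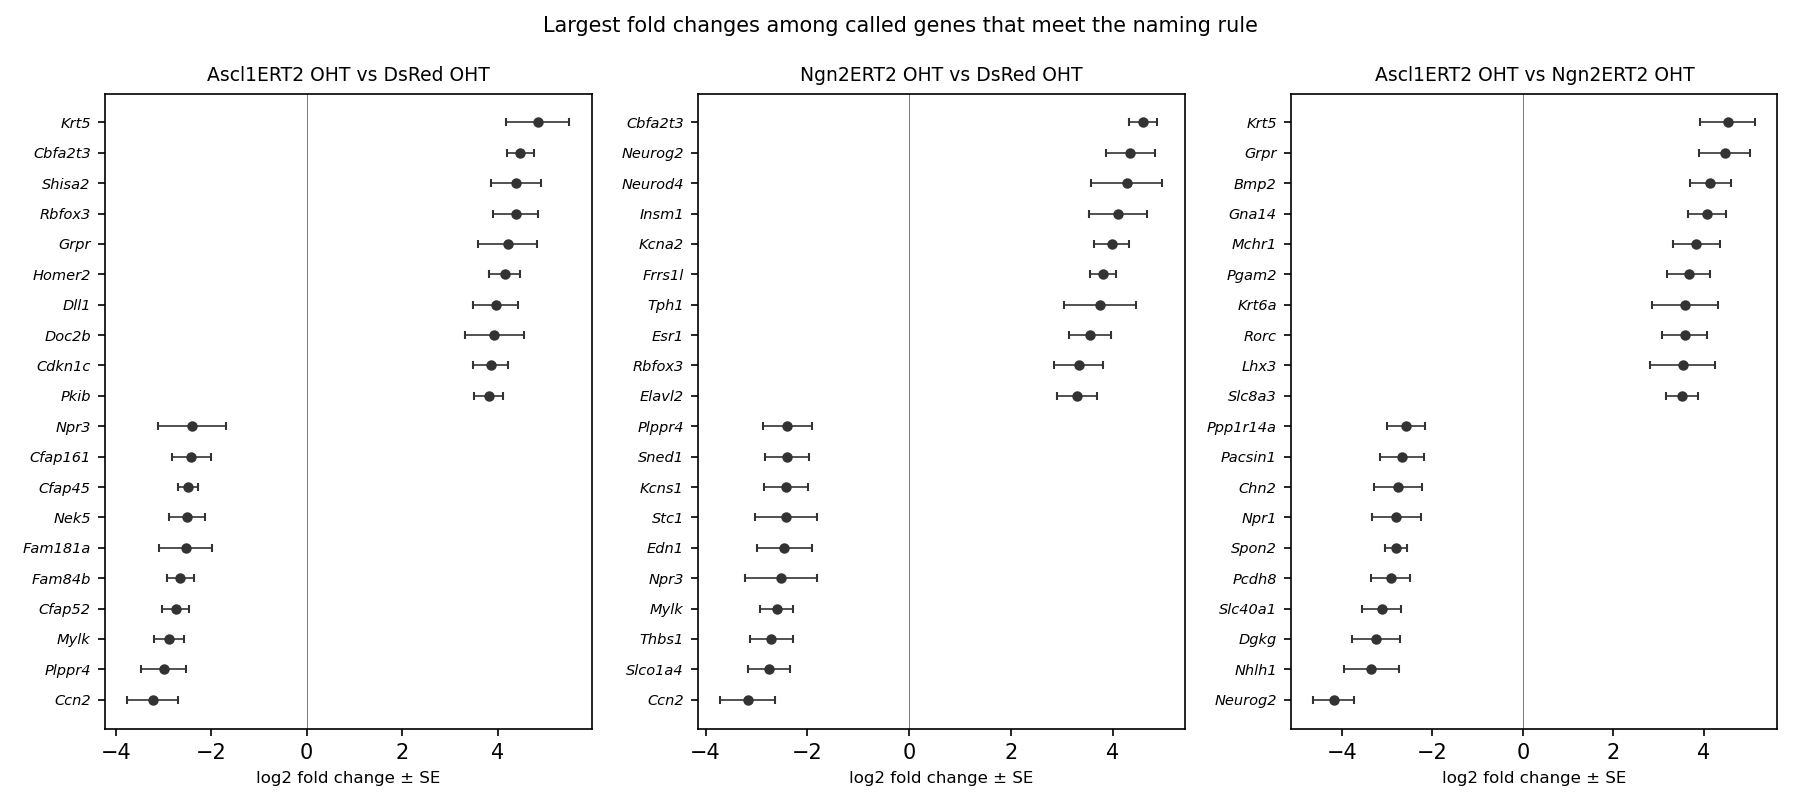
Log2 fold changes of log2(normalised count + 1) with SE (horizontal axes) of the 10 highest and 10 lowest genes that met the naming rule in each comparison with OHT. Cbfa2t3 stood at 4.48 in Ascl1ERT2 and 4.58 in Ngn2ERT2 cells against DsRed cells, and Ccn2 at -3.22 and -3.17.

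The neurogenic list was led by Cbfa2t3 and Sox11, a transcription factor of immature neurons (3.11 ± 0.26, adjusted p = 1.06e-06), and Insm1, a zinc finger factor of neuronal progenitors, also rose (3.29 ± 0.56, adjusted p = 8.09e-04). Neurod4, a proneural target, had a log2 fold change of 2.14 ± 0.70, adjusted p = 0.0494, on 3 reads in the DsRed OHT libraries, and its ratio of means was 9.27 (95% counting interval 3.17 to 45.0). Of its members 19 rose adjusted over the list alone, and camera placed the list above other genes (adjusted p = 1.07e-14, and adjusted p = 0.0571 with an estimated correlation). Of the Notch pathway genes 6 of 21 rose and 1 fell (7 and 1 adjusted over the list alone). They included Hes6, a repressor that favours neuronal differentiation, at 1.70 ± 0.13, adjusted p = 2.65e-07 (ENSMUSG00000067071, chromosome 1, 91411483 to 91414038, minus strand), and the ligand Dll3 at 2.20 ± 0.43, adjusted p = 0.00253. The camera adjusted p was 4.22e-04, and adjusted p = 0.271 with an estimated correlation. The neuronal cytoskeleton, adhesion and synapse genes had 10 of 36 higher and 1 lower, the same counts adjusted over the list alone. These included the complexin gene Cplx2 (0.97 ± 0.18, adjusted p = 0.00162) and the microtubule protein gene Dcx (2.28 ± 0.65, adjusted p = 0.0248). Their camera result (adjusted p = 0.0121, and adjusted p = 0.415 with an estimated correlation) was lost without Ascl1ERT2 OHT 3 or DsRed OHT 3 (adjusted p 0.0517 to 0.0625). Calls lost without single libraries were those of Neurod4 without Ascl1ERT2 OHT 2, 3, 4 or 5 or DsRed OHT 2, 3 or 4 (0.0535 to 0.171) and Dcx without Ascl1ERT2 OHT 2 or DsRed OHT 2 or 3 (0.0847 to 0.0962). Without the 3 libraries set apart by oligodendrocyte transcripts, 6 cytoskeleton, adhesion and synapse genes rose and 2 fell.

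Of 9 tested inhibitory neuron genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with the transcription factor Gata3 at 2.51 ± 0.67, adjusted p = 0.0172 and Gbx2 at -1.68 ± 0.28, adjusted p = 7.10e-04, and camera did not call the list (adjusted p = 0.541). The number that rose was 0 without Ascl1ERT2 OHT 2 or 4 or DsRed OHT 2 and 1 without DsRed OHT 3 or 4. The number that fell was 1 without Ascl1ERT2 OHT 2, 4 or 5 or DsRed OHT 3 or 4, and the call of Gata3 was lost without Ascl1ERT2 OHT 2 or 4 or DsRed OHT 2 or 4 (0.0560 to 0.0715). The excitatory and the spinal V2 interneuron lists each had 2 of 6 members higher and none lower (2 and 4 adjusted over the list alone), with camera adjusted p = 0.197 and 0.0155, the latter at adjusted p = 0.226 with an estimated correlation. The excitatory count was 0 without DsRed OHT 2 and 1 without Ascl1ERT2 OHT 2 or 4 or DsRed OHT 3 or 4, and the V2 count was 0 without DsRed OHT 2 and 1 without Ascl1ERT2 OHT 2 or 4 or DsRed OHT 4.

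Fgfr3, a growth factor receptor of astrocytes, fell (-1.63 ± 0.15, adjusted p = 2.20e-06), whereas Nfix, a transcription factor of gliogenesis, rose (1.45 ± 0.19, adjusted p = 1.01e-04). Of the astrocyte genes 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.34e-05, and adjusted p = 0.415 with an estimated correlation). Gfap, the astrocytic intermediate filament gene, had 1711 ± 315 counts against 2760.0 ± 679 (-0.68 ± 0.38, adjusted p = 0.269). The glial factor Sox9 had -0.46 ± 0.18, adjusted p = 0.110, and neither gene was called. The ependymal genes included Foxj1, the master factor of motile cilia (-1.16 ± 0.14, adjusted p = 3.16e-05), and Dynlrb2, a dynein light chain gene (-1.56 ± 0.19, adjusted p = 3.45e-05). In all 9 of 10 fell adjusted over the list alone, with a camera adjusted p of 2.86e-09 and adjusted p = 0.0571 with an estimated correlation. Of 17 oligodendrocyte lineage genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.859). Olig2 had 1.77 ± 0.29, adjusted p = 6.93e-04 and Sox8 1.97 ± 0.34, adjusted p = 9.44e-04. Without the 3 libraries that held more oligodendrocyte RNA 2 rose and 2 fell, and without single libraries the number that fell was 0 without Ascl1ERT2 OHT 2 or 5 or DsRed OHT 2 and 2 without Ascl1ERT2 OHT 3.

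Of 16 fibroblast, pericyte and smooth muscle genes 1 rose and 4 fell (1 and 8 adjusted over the list alone), among them the calponin gene Cnn1 (-1.91 ± 0.22, adjusted p = 3.04e-05) and the smooth muscle actin gene Acta2 (-0.88 ± 0.21, adjusted p = 0.00927). The number that fell was 2 without DsRed OHT 2 and 7 without DsRed OHT 4, and 8 without the 3 libraries. The camera adjusted p was 0.0119, adjusted p = 0.415 with an estimated correlation, and the call was lost without DsRed OHT 3 (adjusted p = 0.0914). Microglia and macrophage genes had 1 of 18 lower, also adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.578 with an estimated correlation). Without DsRed OHT 4, which held the most Aif1, this camera result had an adjusted p of 0.737 in the other direction. The interferon response genes had 2 of 22 lower and none adjusted over the list alone (camera adjusted p = 3.40e-04, and adjusted p = 0.564 with an estimated correlation), and lost that call without DsRed OHT 4 (adjusted p = 0.219). The number called lower was 0 without Ascl1ERT2 OHT 2 or 4 or DsRed OHT 2 or 4 and 1 without Ascl1ERT2 OHT 3.

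The cell cycle inhibitors had 7 of 16 higher and none lower, also adjusted over the list alone. They included Cdkn1c and the antiproliferative gene Btg1 (1.50 ± 0.28, adjusted p = 0.00177). The camera adjusted p was 0.00705, and adjusted p = 0.415 with an estimated correlation. Their number was 4 without DsRed OHT 2 or 3. Of 23 S-phase genes 3 rose, also adjusted over the list alone, including the replication helicase genes Mcm7 (0.64 ± 0.17, adjusted p = 0.0162) and Mcm2 (0.85 ± 0.24, adjusted p = 0.0231). Their number was 0 without DsRed OHT 2 and 1 without Ascl1ERT2 OHT 3 or DsRed OHT 3 or 4. Of 28 G2 and mitosis genes 3 rose (18 adjusted over the list alone), including Aurka (0.95 ± 0.25, adjusted p = 0.0150) and Ube2c (0.73 ± 0.23, adjusted p = 0.0393), both of which act in mitosis. That number was 0 without DsRed OHT 2, 1 without Ascl1ERT2 OHT 3 or 5 or DsRed OHT 4 and 21 without Ascl1ERT2 OHT 4, and 0 without the 3 libraries. The camera adjusted p was 0.00699 for S phase, lost without Ascl1ERT2 OHT 3 (adjusted p = 0.243), and 8.15e-07 for G2 and mitosis (adjusted p = 0.578 and 0.415 with an estimated correlation). Mki67, a marker of cycling cells, was not called (0.76 ± 0.29, adjusted p = 0.0947). Gene calls lost without single libraries were those of Mcm7 without DsRed OHT 2 (0.0985), Mcm2 without Ascl1ERT2 OHT 3 or DsRed OHT 2, 3 or 4 (0.0508 to 0.0745), Aurka without DsRed OHT 2 (0.0869) and Ube2c without Ascl1ERT2 OHT 3 or 5 or DsRed OHT 2, 3 or 4 (0.0752 to 0.137).

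Id1 and Id2, inhibitors of basic helix-loop-helix factors, were among 5 of 13 BMP and Id genes that rose while 4 fell, also adjusted over the list alone. Their log2 fold changes were 2.44 ± 0.16, adjusted p = 8.26e-08 and 2.15 ± 0.19, adjusted p = 1.46e-06. The list's median was -0.40 and its mean 0.10, and camera did not call it (adjusted p = 0.614). The number that fell was 2 without DsRed OHT 2. Cholesterol synthesis genes included Lss, lanosterol synthase (-1.44 ± 0.25, adjusted p = 8.75e-04), and Cyp51, lanosterol demethylase (-1.03 ± 0.20, adjusted p = 0.00200). Adjusted over the list alone 14 of 22 fell, with a camera adjusted p of 1.28e-07 and adjusted p = 0.367 with an estimated correlation. The mitochondrially encoded RNAs had 4 of 13 higher (8 adjusted over the list alone), including the complex I subunit genes mt-Nd3 (0.95 ± 0.21, adjusted p = 0.00583) and mt-Nd4l (0.82 ± 0.20, adjusted p = 0.00913). The reads of mt-Nd4l share sequence with mt-Nd4, which has no value in the table. The camera adjusted p of the list was 1.13e-04, and adjusted p = 0.415 with an estimated correlation, and 1 rose without the 3 libraries.

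The remaining lists had few called members and no camera call against DsRed cells. Oxidative stress genes had 1 of 18 higher and 2 lower (3 and 5 adjusted over the list alone). They included Gclc, which makes glutathione (-1.32 ± 0.20, adjusted p = 3.27e-04), and the quinone reductase gene Nqo1 (-0.92 ± 0.29, adjusted p = 0.0398), whose call was lost without Ascl1ERT2 OHT 2, 3, 4 or 5 or DsRed OHT 2 or 3 (0.0626 to 0.155). Oestrogen receptor targets had 1 of 11 higher, which was Esr1 itself (2.28 ± 0.41, adjusted p = 0.00130), and 2 lower, including the retinoic acid receptor gene Rara (-1.02 ± 0.24, adjusted p = 0.00832), whose call was lost without DsRed OHT 3 (0.0522). Endothelial (1 of 6 lower), Schwann cell (1 of 6 higher and 1 lower, median -0.37 and mean 0.14), unfolded protein response (1 of 20 lower), immediate early (2 of 21 higher) and RNA quality genes (0 of 9) had camera adjusted p values of 0.234, 0.541, 0.232, 0.478 and 0.515. Their counts were the same adjusted over the list alone. Without the 3 libraries together Neurod4, Dcx, Gata3, Mcm2, Aurka, Ube2c and mt-Nd4l lost their calls (adjusted p 0.0577 to 0.133), at log2 fold changes of 2.23, 2.58, 2.25, 0.75, 0.75, 0.53 and 0.69. Numbers of called members below 3 are not followed library by library for these lists.

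**Figure D4:**
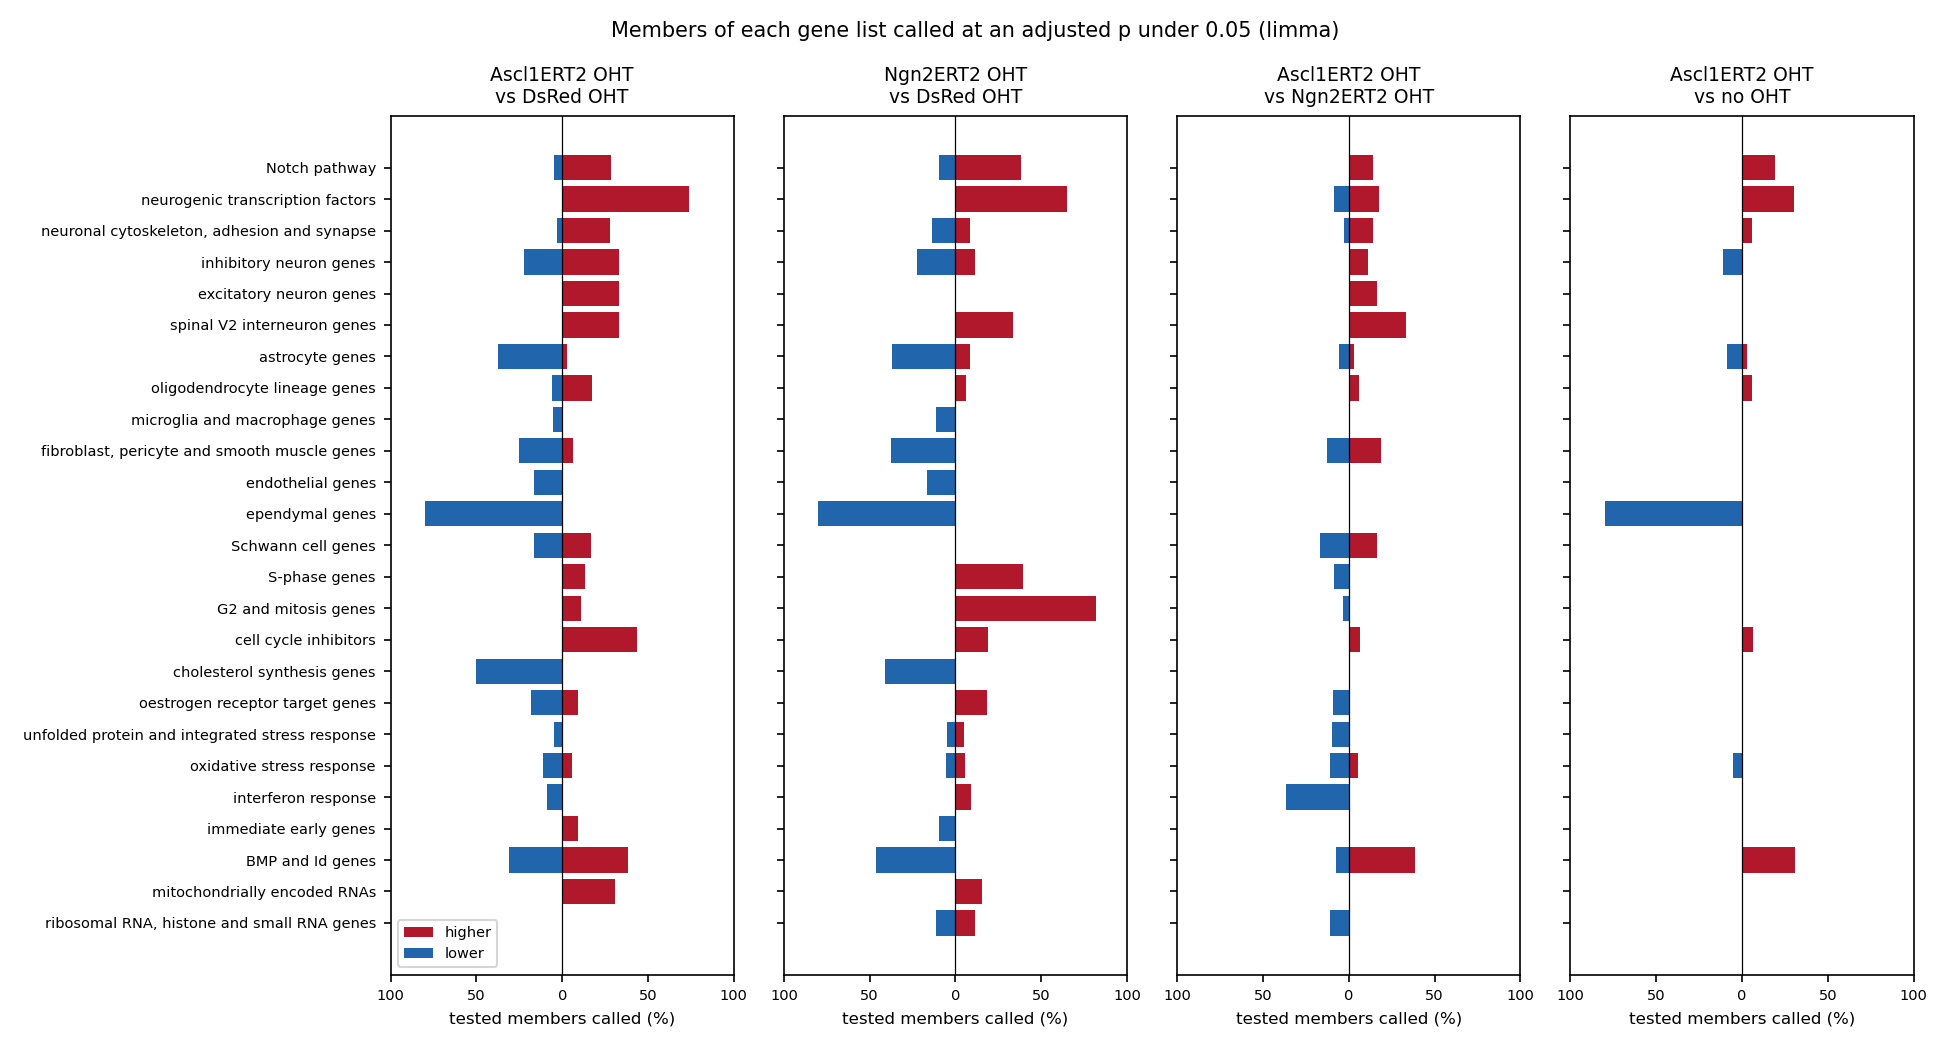
Percent of the tested members of each of the 25 gene lists (vertical axis) called higher (to the right, red) or lower (to the left, blue) by limma in 4 comparisons (horizontal axes, in percent). With OHT, 17 neurogenic factors were called higher and 8 ependymal genes lower in Ascl1ERT2 than in DsRed cells (15 and 8 in Ngn2ERT2 cells).

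In Ngn2ERT2 cells with OHT 15 of 23 neurogenic transcription factors and 23 of 28 G2 and mitosis genes rose relative to DsRed cells with OHT, and 8 of 10 ependymal genes fell. Their camera calls were lost with an estimated correlation (adjusted p = 0.0625, 0.337 and 0.0625). The number of G2 and mitosis genes was 11 without DsRed OHT 2. Of 15293 genes tested with limma, 898 were higher and 1221 lower in Ngn2ERT2 cells (n = 4) than in DsRed cells (n = 3) at an adjusted p under 0.05, of which 446 and 572 differed by at least 2-fold. The count fell to 1055 without DsRed OHT 2.

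Cbfa2t3 again had the highest log2 fold change under the naming rule (4.58 ± 0.28, adjusted p = 1.12e-07, from 9.21 ± 2.33 to 252 ± 93.5 counts, SD). Neurog2 itself followed (4.34 ± 0.48, adjusted p = 5.13e-05), then Neurod4 (4.27 ± 0.70, adjusted p = 9.99e-04), Insm1 (4.10 ± 0.56, adjusted p = 2.52e-04, ENSMUSG00000068154, chromosome 2, 146221921 to 146225020, plus strand) and Kcna2, a voltage-gated potassium channel gene (3.98 ± 0.35, adjusted p = 3.74e-06). Neurod4 had 3 reads in the DsRed OHT libraries, and its ratio of means was 64.9 (95% counting interval 22.2 to 314). Frrs1l, which helps assemble glutamate receptors (3.81 ± 0.25), Tph1, tryptophan hydroxylase (3.74 ± 0.70), Esr1 (3.55 ± 0.41), Rbfox3 (3.33 ± 0.48) and the neuronal RNA-binding protein gene Elavl2 (3.30 ± 0.39) completed the 10 highest. Among the 10 lowest were Ccn2 (-3.17 ± 0.53, adjusted p = 0.00158), the anion transporter gene Slco1a4 (-2.76 ± 0.41), thrombospondin 1, Thbs1 (-2.71 ± 0.42), Mylk (-2.61 ± 0.32) and the vasoconstrictor gene Edn1 (-2.45 ± 0.54). The others were Npr3 (-2.51 ± 0.71), stanniocalcin 1, Stc1 (-2.43 ± 0.61), the potassium channel subunit gene Kcns1 (-2.42 ± 0.43), the matrix gene Sned1 (-2.40 ± 0.44) and Plppr4 (-2.39 ± 0.47). Calls were lost for Npr3 without Ngn2ERT2 OHT 1 or 4 or DsRed OHT 2, 3 or 4 (0.0519 to 0.118) and Stc1 without DsRed OHT 2 or 3 (0.0755 to 0.0771).

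The neurogenic list had 17 members higher and 1 lower adjusted over the list alone (camera adjusted p = 1.40e-14, and adjusted p = 0.0625 with an estimated correlation), led by Cbfa2t3 and Sox4, a factor of neuronal differentiation (2.83 ± 0.32, adjusted p = 7.70e-05). Of 21 Notch pathway genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), including Hes6 (1.85 ± 0.13, adjusted p = 2.09e-07) and the ligand Jag1 (2.42 ± 0.33, adjusted p = 2.53e-04). Without DsRed OHT 2 the numbers were 5 and 1. The camera adjusted p was 0.0154, and adjusted p = 0.405 with an estimated correlation. Dll1 had 1.87 ± 0.47, adjusted p = 0.0146, Ascl1 had 1.05 ± 0.26, adjusted p = 0.0130, and Dll3 was not called (0.72 ± 0.43, adjusted p = 0.275). Calls were lost for Dll1 without DsRed OHT 2 (0.0730) and Ascl1 without DsRed OHT 2 (0.0912). Cytoskeleton, adhesion and synapse genes had 3 of 36 higher, including Cplx2 (1.28 ± 0.18, adjusted p = 3.18e-04), and 5 lower (4 and 5 adjusted over the list alone). They had median -0.06, mean 0.10 and camera adjusted p = 0.840. The number that fell was 2 without Ngn2ERT2 OHT 1 or 4 or DsRed OHT 2 and 3 without Ngn2ERT2 OHT 3 or DsRed OHT 3. Dcx was not called (1.87 ± 0.65, adjusted p = 0.0638).

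The V2 interneuron genes had 2 of 6 higher, including Foxn4, a factor of V2 and retinal progenitors (3.19 ± 0.58, adjusted p = 0.00205), whose ratio of means on 3 DsRed reads was 26.8 (95% counting interval 9.17 to 130.0). The inhibitory neuron genes had 1 of 9 higher and 2 lower, including Gbx2 (-1.04 ± 0.28, adjusted p = 0.0221), and none of the 6 excitatory genes was called. Camera adjusted p values were 0.260, 0.840 and 0.772, and all 3 counts were the same adjusted over the list alone. The call of Gbx2 was lost without Ngn2ERT2 OHT 1 or DsRed OHT 2, 3 or 4 (0.0561 to 0.0701) and without the 3 libraries together (0.0534, at a log2 fold change of -1.11).

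Of 35 astrocyte genes 3 rose and 13 fell (4 and 17 adjusted over the list alone), including Fgfr3 (-1.08 ± 0.15, adjusted p = 2.71e-04) and the metallothionein gene Mt2 (-1.46 ± 0.23, adjusted p = 7.14e-04). The number that fell was 8 without DsRed OHT 2, and the number that rose was 1 without Ngn2ERT2 OHT 1 or DsRed OHT 2 or 3. Gfap (0.42 ± 0.38, adjusted p = 0.491) and Sox9 (-0.41 ± 0.18, adjusted p = 0.145) were not called. Ependymal genes included Foxj1 (-1.01 ± 0.14, adjusted p = 2.26e-04) and Dynlrb2 (-1.22 ± 0.19, adjusted p = 5.77e-04), and 9 fell adjusted over the list alone. Of 16 fibroblast, pericyte and smooth muscle genes 6 fell (8 adjusted over the list alone), including Cnn1 (-1.90 ± 0.22, adjusted p = 7.70e-05) and Acta2 (-1.11 ± 0.21, adjusted p = 0.00271). Their number was 2 without DsRed OHT 2 and 10 without DsRed OHT 4. Camera adjusted p values were 2.73e-05 for astrocyte, 1.14e-08 for ependymal and 0.00101 for fibroblast genes (adjusted p = 0.434, 0.0625 and 0.405 with an estimated correlation). Microglia and macrophage genes had 2 of 18 lower (8 adjusted over the list alone), with camera adjusted p = 5.75e-05 and adjusted p = 0.434 with an estimated correlation, a call lost without DsRed OHT 4 (adjusted p = 0.111). Olig2 was the only oligodendrocyte lineage gene called, of 17 and also adjusted over the list alone (1.34 ± 0.29, adjusted p = 0.00665, camera adjusted p = 0.772).

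**Figure D5:**
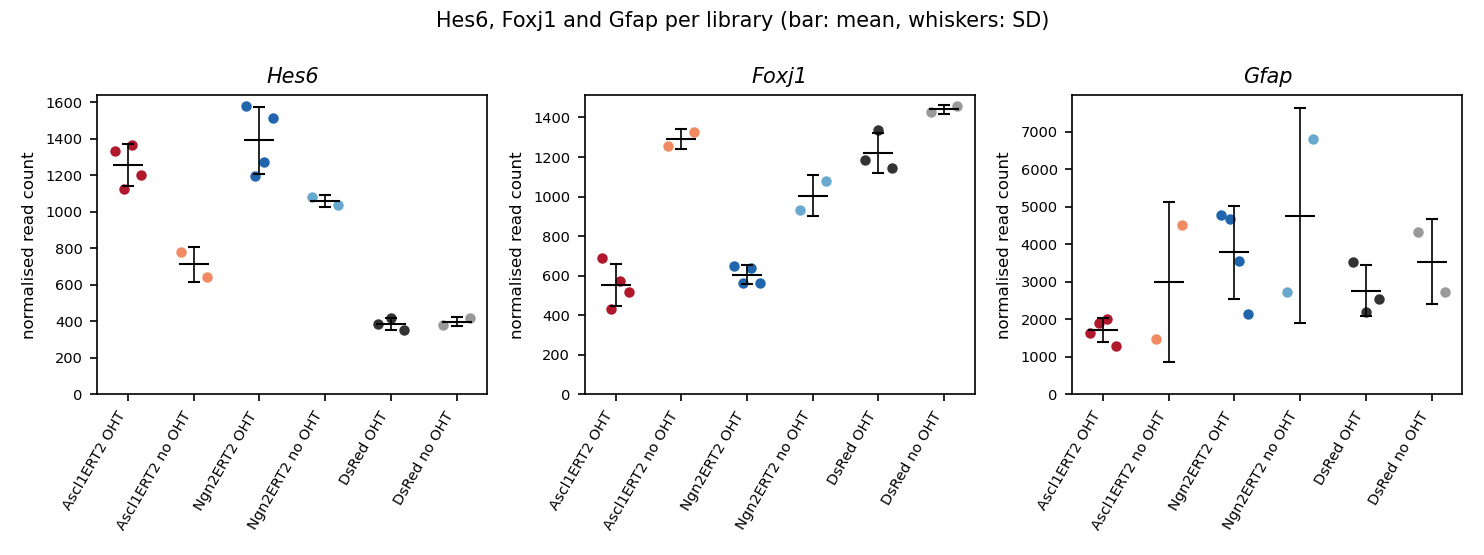
Normalised read counts of Hes6, Foxj1 and Gfap (vertical axes) in each library, by group (horizontal axis), with a point per library, a bar at the mean and whiskers of 1 SD. With OHT, Hes6 averaged 1257 in Ascl1ERT2, 1392 in Ngn2ERT2 and 385 in DsRed cells.

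Among S-phase genes 9 of 23 rose (15 adjusted over the list alone), led by E2f1, a driver of S-phase entry (1.21 ± 0.18, adjusted p = 4.84e-04), and the helicase gene Mcm6 (1.25 ± 0.22, adjusted p = 0.00185). Their number was 4 without Ngn2ERT2 OHT 2 or DsRed OHT 2 or 3 and 5 without Ngn2ERT2 OHT 3. The G2 and mitosis genes included Ube2c (1.27 ± 0.23, adjusted p = 0.00182) and Hmmr (1.34 ± 0.24, adjusted p = 0.00200), a spindle gene, and 27 of 28 rose adjusted over the list alone. Camera adjusted p values were 1.00e-08 and 1.25e-16, and adjusted p = 0.405 and 0.337 with an estimated correlation. Mki67 rose as well (1.41 ± 0.29, adjusted p = 0.00498). Cell cycle inhibitors had 3 of 16 higher (5 adjusted over the list alone), including Btg1 (1.85 ± 0.28, adjusted p = 5.95e-04) and Cdkn1b (0.67 ± 0.15, adjusted p = 0.00635), which encodes p27, without a camera call (adjusted p = 0.250).

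Cholesterol synthesis genes had 9 of 22 lower (14 adjusted over the list alone), including squalene epoxidase, Sqle (-1.02 ± 0.14, adjusted p = 2.29e-04), and Cyp51 (-1.13 ± 0.20, adjusted p = 0.00158). Their number was 4 without DsRed OHT 2 and 5 without Ngn2ERT2 OHT 4. Of 13 BMP and Id genes 6 fell (7 adjusted over the list alone), including the BMP antagonist gene Nog (-1.62 ± 0.30, adjusted p = 0.00217) and the pseudoreceptor gene Bambi (-1.48 ± 0.23, adjusted p = 5.95e-04), and none rose. Their camera adjusted p values were 1.06e-06 and 8.69e-04, and adjusted p = 0.405 and 0.150 with an estimated correlation. The interferon response had 2 of 22 higher and none adjusted over the list alone (camera adjusted p = 0.0321, and adjusted p = 0.753 with an estimated correlation), a call lost without Ngn2ERT2 OHT 1, 2 or 3 or DsRed OHT 2 or 3 (adjusted p 0.0692 to 0.572). Mitochondrially encoded RNAs had 2 of 13 higher, also adjusted over the list alone (camera adjusted p = 0.0362, and adjusted p = 0.753 with an estimated correlation), a call lost without Ngn2ERT2 OHT 1 or DsRed OHT 4 (adjusted p 0.282 to 0.374). No camera call was made for endothelial (1 of 6 lower, adjusted p = 0.562), Schwann cell (0 of 6, 0.840), immediate early (2 of 21 lower, 0.139), oxidative stress (1 of 18 higher and 1 lower, 0.522) or RNA quality genes (1 of 9 higher and 1 lower, 0.310). Nor was one made for oestrogen receptor targets (2 of 11 higher, median -0.22, mean 0.16, 0.840) or the unfolded protein response (1 of 20 higher and 1 lower, median -0.01, mean 0.06, 0.772). Adjusted over the list alone these counts were the same, apart from 1 oestrogen receptor target that fell.

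Many of the same genes were called with both factors. Relative to DsRed cells with OHT, 376 genes were higher with both factors, where 64.1 would be shared by independent lists, 657 were lower (94.1 by the same reckoning), and 14 were called in opposite directions. Both comparisons use the same 3 DsRed libraries, which alone makes fold changes correlate. The correlation of fold changes was 0.642 over the 15293 genes, and 0.571 in simulations with shared controls and no true effects. The covariance was 0.264 against 0.0531 in those simulations. Part of the overlap may thus come from the shared controls, which cannot be split into parts of 2, and without DsRed OHT 2 the 1033 shared genes became 557.

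Compared directly with OHT, Ascl1ERT2 cells held more RNA of the keratin genes Krt5 and Krt6a than Ngn2ERT2 cells. Of the BMP and Id genes 5 of 13 were higher and 1 lower in Ascl1ERT2 cells, also adjusted over the list alone, and of the interferon response genes 8 of 22 were lower (20 adjusted over the list alone). Both camera calls were lost with an estimated correlation (adjusted p = 0.161 and 0.570). The number of interferon genes that fell was 2 without Ascl1ERT2 OHT 2 or Ngn2ERT2 OHT 3, 3 without Ngn2ERT2 OHT 1 or 2 or Ascl1ERT2 OHT 3 or 4 and 19 without Ngn2ERT2 OHT 4, and 5 without the 3 libraries. Of 15293 genes tested with limma, 644 were higher and 425 lower in Ascl1ERT2 cells (n = 4) than in Ngn2ERT2 cells (n = 4) at an adjusted p under 0.05, of which 372 and 198 differed by at least 2-fold. The count was 693 without Ascl1ERT2 OHT 2 and 708 without Ascl1ERT2 OHT 4.

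Higher in Ascl1ERT2 cells were Krt5 (4.53 ± 0.61, adjusted p = 1.94e-04), Grpr (4.46 ± 0.57, adjusted p = 1.15e-04), the growth factor gene Bmp2 (4.15 ± 0.45, adjusted p = 2.53e-05), and the G protein subunit gene Gna14 (4.07 ± 0.41, adjusted p = 1.03e-05). They were followed by the receptor gene Mchr1 (3.83 ± 0.52), the glycolytic enzyme gene Pgam2 (3.67 ± 0.48), a further keratin gene, Krt6a (3.59 ± 0.73), the nuclear receptor gene Rorc (3.58 ± 0.49), the motor neuron and V2 factor Lhx3 (3.54 ± 0.72) and the sodium-calcium exchanger gene Slc8a3 (3.52 ± 0.35). Grpr had 1 read and Lhx3 had 2 in the 4 Ngn2ERT2 libraries, with ratios of means of 94.5 (95% counting interval 17.0 to 3732) and 40.6 (95% counting interval 11.2 to 335), the latter 16.9 without Ascl1ERT2 OHT 4. Apart from Neurog2 (-4.18 ± 0.45, adjusted p = 2.00e-05), the genes lower in Ascl1ERT2 cells were led by Nhlh1, a basic helix-loop-helix factor of young neurons (-3.35 ± 0.61, adjusted p = 0.00239), the lipid kinase gene Dgkg (-3.24 ± 0.54, adjusted p = 0.00109), and ferroportin, Slc40a1 (-3.12 ± 0.43). Next were the protocadherin gene Pcdh8 (-2.92 ± 0.43) and the matrix gene Spon2 (-2.81 ± 0.25, from 497 ± 216 to 65.2 ± 10.0 counts, SD). They also included the guanylyl cyclase gene Npr1 (-2.80 ± 0.54), Chn2 (-2.76 ± 0.53), the synaptic endocytosis gene Pacsin1 (-2.67 ± 0.48) and the phosphatase inhibitor gene Ppp1r14a (-2.58 ± 0.42). None of these 20 calls depended on a single library.

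Id1 and Id3 had log2 fold changes of 2.27 ± 0.15, adjusted p = 1.24e-07 and 1.95 ± 0.15, adjusted p = 9.08e-07, and the BMP and Id list had a camera adjusted p of 9.50e-05 (adjusted p = 0.161 with an estimated correlation). The chemokine gene Cxcl10 (-2.25 ± 0.47, adjusted p = 0.00626) and the GTPase gene Gbp2 (-1.58 ± 0.34, adjusted p = 0.00912) led the interferon response (camera adjusted p = 1.37e-11, and adjusted p = 0.570 with an estimated correlation). Of the S-phase genes 2 of 23 fell (4 adjusted over the list alone) and of the G2 and mitosis genes 1 of 28 (none adjusted over the list alone), with camera adjusted p values of 1.72e-04 and 6.66e-07 (adjusted p = 0.830 for both with an estimated correlation). Without Ascl1ERT2 OHT 3 the numbers that fell were 6 and 14, and without all 3 libraries 5 and 6.

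Notch pathway genes had 3 of 21 higher, also adjusted over the list alone, including the modifier gene Lfng (1.40 ± 0.19, adjusted p = 1.77e-04) and Dll1 (2.09 ± 0.43, adjusted p = 0.00660), without a camera call (adjusted p = 0.381). Dll3 (1.48 ± 0.40, adjusted p = 0.0325) and Ascl1 (0.88 ± 0.24, adjusted p = 0.0336) were also higher in Ascl1ERT2 cells. Neurogenic transcription factors had 4 of 23 higher, including Atoh8 (1.68 ± 0.26, adjusted p = 6.38e-04), and 2 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.697). The number that rose was 1 without Ascl1ERT2 OHT 2 and 2 without Ngn2ERT2 OHT 3 or 4 or Ascl1ERT2 OHT 4. Neurod4 (-2.12 ± 0.65, adjusted p = 0.0601), Insm1 (-0.81 ± 0.52, adjusted p = 0.399), Hes6 (-0.14 ± 0.12, adjusted p = 0.519) and Dcx (0.41 ± 0.60, adjusted p = 0.747) were not called. Cytoskeleton, adhesion and synapse genes had 5 of 36 higher and 1 lower (8 and 2 adjusted over the list alone), including the neurofilament gene Nefl (3.33 ± 0.44, adjusted p = 1.77e-04) and the axon guidance gene Dpysl5 (2.16 ± 0.31, adjusted p = 3.78e-04). Their camera call (adjusted p = 0.0300, and adjusted p = 0.716 with an estimated correlation) was lost without Ascl1ERT2 OHT 3 or Ngn2ERT2 OHT 3 or 4 (adjusted p 0.0664 to 0.114). Excitatory neuron genes had 1 of 6 higher (2 adjusted over the list alone) and camera adjusted p = 0.0481 (adjusted p = 0.513 with an estimated correlation), lost without Ngn2ERT2 OHT 1 or 2 or Ascl1ERT2 OHT 3 or 4 (adjusted p 0.0670 to 0.114). Calls were lost for Dll3 without Ngn2ERT2 OHT 2 or 3 or Ascl1ERT2 OHT 2, 3 or 4 (0.0783 to 0.102) and Ascl1 without Ngn2ERT2 OHT 2 or 4 or Ascl1ERT2 OHT 2, 4 or 5 (0.0771 to 0.102), and without the 3 libraries for Dll3 (0.182, at 1.09) and Ascl1 (0.0857, at 0.79).

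In the fibroblast, pericyte and smooth muscle list 3 of 16 rose, including the vitronectin gene Vtn (1.15 ± 0.30, adjusted p = 0.0277) and the collagen gene Col1a1 (0.98 ± 0.26, adjusted p = 0.0286), and 2 fell, also adjusted over the list alone (camera adjusted p = 0.463). The number that rose was 1 without Ngn2ERT2 OHT 2 or 4 or Ascl1ERT2 OHT 2, 4 or 5. In the oxidative stress list 1 of 18 rose and 2 fell (3 and 4 adjusted over the list alone), including Gclm, the partner of Gclc (-0.57 ± 0.12, adjusted p = 0.00600), and Nqo1 (-1.16 ± 0.27, adjusted p = 0.0124). The list had median 0.09, mean 0.04, camera downward and adjusted p = 0.961. In the astrocyte list 1 of 35 rose and 2 fell, also adjusted over the list alone, including Fgfr3 (-0.55 ± 0.14, adjusted p = 0.0201). It had median 0.04, mean -0.02 and camera adjusted p = 0.724. Calls were lost for Fgfr3 without Ngn2ERT2 OHT 2 or Ascl1ERT2 OHT 2 or 4 (0.0606 to 0.0692), Vtn without Ngn2ERT2 OHT 2 or 4 or Ascl1ERT2 OHT 4 or 5 (0.0593 to 0.0929) and Col1a1 without Ascl1ERT2 OHT 2 or 5 or Ngn2ERT2 OHT 4 (0.0561 to 0.110), and without the 3 libraries for Fgfr3 (0.0519, at -0.48). Mitochondrially encoded RNAs had 0 of 13 called by limma, and a camera adjusted p of 0.0481 (adjusted p = 0.830 with an estimated correlation) that was lost without Ngn2ERT2 OHT 2, 3 or 4 or Ascl1ERT2 OHT 2 or 3 (adjusted p 0.0898 to 0.209). Gfap (-1.10 ± 0.35, adjusted p = 0.0758), Sox9 (-0.05 ± 0.17, adjusted p = 0.903), Olig2 (0.42 ± 0.27, adjusted p = 0.397), Esr1 (-1.27 ± 0.38, adjusted p = 0.0534) and Mki67 (-0.64 ± 0.27, adjusted p = 0.185) were not called.

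The other lists had no camera call between the factors. Inhibitory (1 of 9 higher, adjusted p = 0.834), V2 (2 of 6 higher, 0.497), oligodendrocyte (1 of 17 higher, 0.724), and cell cycle inhibitor genes (1 of 16 higher, 0.0676) had few calls. So did Schwann cell (1 of 6 higher and 1 lower, 0.925), oestrogen receptor target (1 of 11 lower, 0.331), unfolded protein response (2 of 20 lower, 0.0655) and RNA quality genes (1 of 9 lower, 0.697). Microglia (0.0676), endothelial (0.724), ependymal (0.331), cholesterol synthesis (0.724) and immediate early genes (0.381) had 0 calls by limma. Adjusted over the list alone 1 inhibitory and 1 V2 gene also fell, 3 oestrogen receptor targets fell, and the others were the same. Median and mean differed in sign for oestrogen receptor targets (0.04 and -0.20) and RNA quality genes (0.01 and -0.13), and the Schwann cell list had a median of 0.12 with camera downward.

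Ascl1ERT2 cells held more neurogenic and less ciliary RNA with OHT than without. Cdkn1c went from 139 ± 13.8 to 2122 ± 1116 counts (SD, 3.77 ± 0.42, adjusted p = 1.37e-04), and 8 of 10 ependymal genes fell, including Foxj1 (-1.25 ± 0.15, adjusted p = 2.33e-04) and Ccdc153 (-1.66 ± 0.25, adjusted p = 0.00139). Of the neurogenic transcription factors 7 of 23 rose (15 adjusted over the list alone), led by Cbfa2t3 (3.13 ± 0.32, adjusted p = 3.88e-05) and Sox11 (2.60 ± 0.29, adjusted p = 1.32e-04). Of 15293 genes tested with limma, 236 were higher and 188 lower with OHT (n = 4) than without (n = 2), of which 178 and 117 differed by at least 2-fold. These 424 calls became 93 without Ascl1ERT2 no OHT 1, 186 without Ascl1ERT2 no OHT 3, 262 without Ascl1ERT2 OHT 2 and 275 without Ascl1ERT2 OHT 4. The number of ependymal genes that fell was 2 without Ascl1ERT2 no OHT 1, and that of neurogenic factors that rose was 2 without Ascl1ERT2 no OHT 1.

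With OHT the highest fold changes in Ascl1ERT2 cells were also those of Krt5 (4.19 ± 0.75, adjusted p = 0.00504), Flrt1, a cell adhesion gene (3.73 ± 0.34, adjusted p = 1.59e-05), Myt1, a zinc finger factor of neuronal differentiation (3.60 ± 0.64, adjusted p = 0.00504), and Krt6a (3.50 ± 0.90, adjusted p = 0.0440). The lowest were those of the cilia genes Cfap52 (-2.35 ± 0.33, adjusted p = 6.54e-04) and Ccdc113 (-2.33 ± 0.30, adjusted p = 3.25e-04). Also low were Smim5 (-2.18 ± 0.50, adjusted p = 0.0247), the ciliary kinase gene Mak (-2.15 ± 0.34, adjusted p = 0.00207) and the heat shock gene Hspa1b (-1.95 ± 0.49, adjusted p = 0.0399), whose reads are uncertain because Hspa1a is nearly identical. Hes6 (0.82 ± 0.14, adjusted p = 0.00384), Dll1 (2.32 ± 0.53, adjusted p = 0.0251) and Dll3 (2.25 ± 0.49, adjusted p = 0.0186) rose. Ascl1 (0.41 ± 0.29, adjusted p = 0.632), Esr1 (-0.12 ± 0.46, adjusted p = 0.952), Insm1 (1.85 ± 0.64, adjusted p = 0.160), Dcx (1.85 ± 0.74, adjusted p = 0.257) and Gfap (-0.62 ± 0.43, adjusted p = 0.628) were not called. Of the 21 named and called genes 10 lost the call without a single library. Without Ascl1ERT2 no OHT 1 these were Krt5, Dll1, Dll3, Krt6a, Myt1, Smim5, Mak and Hspa1b (adjusted p 0.0735 to 0.383), and without Ascl1ERT2 no OHT 3 they were Hes6, Dll3, Mt2, Krt6a, Smim5 and Hspa1b (0.0654 to 0.233). Without Ascl1ERT2 OHT 2 they were Dll1, Dll3, Krt6a and Smim5 (0.0557 to 0.122), without OHT 4 Dll1, Krt6a and Hspa1b (0.0680 to 0.0928), without OHT 5 Krt6a and Hspa1b (0.0619 to 0.104), and without OHT 3 Hspa1b (0.0787).

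Of the lists, the ependymal one (camera adjusted p = 5.61e-13) and the neurogenic one (5.06e-16) kept their calls with an estimated correlation (adjusted p = 0.0242 and 0.0433), and no other camera call in any comparison did. BMP and Id genes had 4 of 13 higher (5 higher and 1 lower adjusted over the list alone), including Id2 (1.75 ± 0.22, adjusted p = 2.25e-04) and Bmp7 (2.63 ± 0.36, adjusted p = 5.26e-04). Their values had median -0.03, mean 0.55 and camera adjusted p = 0.00800, lost without Ascl1ERT2 no OHT 1 (adjusted p = 0.192). Notch pathway genes had 4 of 21 higher, also adjusted over the list alone (camera adjusted p = 0.00471, lost without Ascl1ERT2 no OHT 1 at 0.342), and their number was 1 without Ascl1ERT2 no OHT 1 or 3 or Ascl1ERT2 OHT 2 and 2 without Ascl1ERT2 OHT 4. Astrocyte genes had 1 higher and 3 of 35 lower (1 and 5 adjusted over the list alone), including Fgfr3 (-1.06 ± 0.17, adjusted p = 0.00228) and Mt2 (-1.41 ± 0.26, adjusted p = 0.00606). The camera call (adjusted p = 1.13e-04) was lost without Ascl1ERT2 no OHT 3 (adjusted p = 0.930). The number of astrocyte genes that fell was 1 without Ascl1ERT2 no OHT 3. Cytoskeleton, adhesion and synapse genes had 2 of 36 higher (9 adjusted over the list alone, camera adjusted p = 2.49e-05). S-phase and G2 and mitosis genes had 0 calls by limma and camera adjusted p values of 5.99e-04, lost without Ascl1ERT2 OHT 3 or Ascl1ERT2 no OHT 3 (adjusted p 0.132 to 0.151), and 1.39e-06. With an estimated correlation adjusted p = 0.261 for BMP and Id, 0.405 for Notch, 0.684 for astrocyte, 0.189 for cytoskeleton, 0.806 for S-phase and 0.684 for G2 and mitosis genes. Of the other lists, called by camera in no case, oligodendrocyte genes and cell cycle inhibitors had 1 member higher each, oxidative stress and inhibitory neuron genes had 1 lower each, and the rest 0 by limma. Adjusted over the list alone, 1 S-phase, inhibitory, excitatory, V2, fibroblast and Schwann cell gene each rose, 1 inhibitory, fibroblast and oestrogen receptor target gene each fell, and 2 oxidative stress genes fell.

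Kcna2 rose with OHT in Ngn2ERT2 cells (3.56 ± 0.39, adjusted p = 9.56e-04, from 16.2 ± 6.92 to 203 ± 69.2 counts, SD), and Ttll7, a tubulin polyglutamylase gene, fell (-1.56 ± 0.23, adjusted p = 0.0266). These were the only 2 genes called by limma of 15293 (n = 4 with OHT and 2 without), while 771 had an unadjusted p under 0.05 and edgeR called 3 and DESeq2 25. The count was 0 without Ngn2ERT2 no OHT 2, 1 without Ngn2ERT2 OHT 1, OHT 4 or no OHT 3, and 4 without OHT 2 or OHT 3. Calls were lost for Kcna2 without Ngn2ERT2 no OHT 2 (0.132) and for Ttll7 without Ngn2ERT2 OHT 1 (0.104), OHT 4 (0.109), no OHT 2 (0.341) or no OHT 3 (0.284), or the 3 libraries (0.0704, at -1.56). Neurog2 (-0.19 ± 0.55), Hes6 (0.39 ± 0.14, adjusted p = 0.761), Insm1 (2.53 ± 0.64, adjusted p = 0.360) and Neurod4 (3.66 ± 0.80, adjusted p = 0.247, ratio of means 30.7 with a 95% counting interval of 10.5 to 149) were not called. Camera called 4 lists without a called member, adjusted over all genes. These were neurogenic factors (adjusted p = 9.64e-09, with 7 members higher adjusted over the list alone), S-phase genes (7.12e-10), G2 and mitosis genes (1.33e-09) and ependymal genes (0.00379, lost without Ngn2ERT2 no OHT 2 at 0.180), at adjusted p = 0.560, 0.748, 0.849 and 0.748 with an estimated correlation.

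In DsRed cells limma called 0 of 15293 genes for OHT (smallest adjusted p 0.992, n = 3 with OHT and 2 without). Of these, 664 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Without DsRed no OHT 3 the count was 14. Camera called mitochondrially encoded RNAs (adjusted p = 1.87e-08), cholesterol synthesis (3.49e-04, lost without DsRed no OHT 1 or DsRed OHT 2 at 0.196 to 0.485), interferon response (4.65e-04, lost without DsRed no OHT 3 or DsRed OHT 4 at 0.0908 to 0.989, the latter in the other direction) and astrocyte genes (4.65e-04, lost without DsRed no OHT 1 at 0.739). It also called cell cycle inhibitors (0.0173, lost without DsRed no OHT 1 or DsRed OHT 4 at 0.155 to 0.485). Further calls were microglia genes (0.0299, lost without DsRed no OHT 3 at 0.653 and turned without DsRed OHT 4) and ependymal genes (0.0382, lost without DsRed no OHT 3 or DsRed OHT 2 or 4 at 0.0591 to 0.633). No member was called, and the adjusted p was 0.760 to 0.874 with an estimated correlation.

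Without OHT, Frrs1l had 234 ± 93.6 counts in Ngn2ERT2 and 18.9 ± 1.97 in DsRed cells (SD, 3.51 ± 0.33, adjusted p = 1.01e-04), Hes6 had 1.41 ± 0.16, adjusted p = 0.00107, and the corepressor genes Cbfa2t3 (2.76 ± 0.36, adjusted p = 0.00304) and Rcor2 (2.25 ± 0.39, adjusted p = 0.0171) were higher. Of 15293 genes tested with limma, 49 were higher and 43 lower (n = 2 in each group). The 92 calls became 3 without DsRed no OHT 1, 4 without Ngn2ERT2 no OHT 3, 19 without Ngn2ERT2 no OHT 2 and 61 without DsRed no OHT 3. Also higher were Neurog2 (3.75 ± 0.64, adjusted p = 0.0171), Tdh (3.23 ± 0.46, adjusted p = 0.00461), Spn (3.17 ± 0.63, adjusted p = 0.0323, ratio of means 15.4 with a 95% counting interval of 5.27 to 74.6, and 7.72 without Ngn2ERT2 no OHT 3) and Esr1 (3.13 ± 0.53, adjusted p = 0.0171). The lowest were Kcns1 (-2.59 ± 0.56, adjusted p = 0.0466), Sntg2 (-2.36 ± 0.50, adjusted p = 0.0453), Alpl (-2.32 ± 0.45, adjusted p = 0.0273) and the monocarboxylate transporter genes Slc16a4 (-2.33 ± 0.45, adjusted p = 0.0266) and Slc16a1 (-2.29 ± 0.30, adjusted p = 0.00298). Of the 13 named genes, all but Frrs1l and Hes6 lost the call in at least 1 case. These were 10 without DsRed no OHT 1 and 10 without Ngn2ERT2 no OHT 3. They were 6 without Ngn2ERT2 no OHT 2 and 6 without DsRed no OHT 3.

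Of the neurogenic transcription factors 3 of 23 rose (8 adjusted over the list alone), of the ependymal genes 2 of 10 fell (9), of the astrocyte genes 1 of 35 fell (10) and of the Notch genes 1 of 21 rose (5 and 2 lower). Camera adjusted p values were 7.08e-08, 1.72e-09, 1.21e-09 and 0.0262, the last lost without DsRed no OHT 3 or Ngn2ERT2 no OHT 3. It also called G2 and mitosis (8.24e-10), S-phase (1.17e-04), interferon (1.17e-04, lost without Ngn2ERT2 no OHT 3 at 0.0933), microglia (0.00104) and BMP and Id genes (0.00163). Cholesterol synthesis (0.0187) and fibroblast genes (0.0382) were also called, both lost without Ngn2ERT2 no OHT 2 or DsRed no OHT 3. Mitochondrially encoded RNAs were called too (0.0371, lost without DsRed no OHT 1 or Ngn2ERT2 no OHT 2). With an estimated correlation the smallest adjusted p was 0.0797, of the ependymal genes.

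Limma called only Gm7332 between Ascl1ERT2 and DsRed cells without OHT (1.30 ± 0.18, adjusted p = 0.0189, n = 2 in each group). It had 208 ± 12.8 counts against 84.2 ± 10.0 (SD) and was named after its values were seen. Hes6 (0.83 ± 0.16, adjusted p = 0.280), Olig2 (1.28 ± 0.38, 0.579) and Dll1 (2.005 ± 0.61, 0.596) were higher but not called. Always-named genes had the same sign as with OHT except Mki67 (-0.22 ± 0.38). Of all genes 982 had an unadjusted p under 0.05, while edgeR called 2 and DESeq2 21. The call of Gm7332 was lost without Ascl1ERT2 no OHT 1 or 3 or DsRed no OHT 1. Camera called astrocyte (8.02e-07, lost without Ascl1ERT2 no OHT 1) and cholesterol synthesis genes (0.00338, lost without DsRed no OHT 3). It called fibroblast genes (0.0153, lost without Ascl1ERT2 no OHT 1 or DsRed no OHT 3). It also called ependymal and neurogenic genes (both 0.0229, lost without Ascl1ERT2 no OHT 3 or DsRed no OHT 3). With an estimated correlation their adjusted p was 0.620.

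Cbfa2t3 (3.91 ± 0.46, adjusted p = 7.93e-04), Pkib (3.86 ± 0.50, adjusted p = 0.00130), Sox11 (2.73 ± 0.43, adjusted p = 0.00863) and Flrt1 (4.06 ± 0.50, adjusted p = 9.16e-04) responded to OHT more in Ascl1ERT2 than in DsRed cells, and no single library decided these 4 calls. In all 41 genes had a higher and 11 a lower response by limma (1410 with an unadjusted p under 0.05), a total that became 9 without DsRed no OHT 1, 15 without Ascl1ERT2 no OHT 1 and 33 without DsRed OHT 2 or DsRed OHT 4. Between the factors the response differed in 16 genes, including Bmp7 (2.84 ± 0.51, adjusted p = 0.0345) and Id1 (1.47 ± 0.26, adjusted p = 0.0304). That total was 3 without Ngn2ERT2 no OHT 3, 4 without Ngn2ERT2 no OHT 2, 5 without Ascl1ERT2 no OHT 1, 7 without Ascl1ERT2 OHT 4, 9 without Ascl1ERT2 OHT 2 and 10 without Ngn2ERT2 OHT 3 or Ascl1ERT2 no OHT 3. Calls were lost for Bmp7 without Ascl1ERT2 no OHT 1 or 3 or Ngn2ERT2 OHT 2, 3 or 4 or Ascl1ERT2 OHT 2 or 4 or Ngn2ERT2 no OHT 2 or 3 (0.0546 to 0.269). Id1 lost its call without Ascl1ERT2 no OHT 1 or Ngn2ERT2 OHT 2 or 4 or Ascl1ERT2 OHT 2, 3, 4 or 5 or Ngn2ERT2 no OHT 2 or 3 (0.0501 to 0.349) and without the 3 libraries (0.0898, at 1.43). Between Ngn2ERT2 and DsRed cells the response differed in 0 genes by limma (smallest adjusted p 0.0569), with 613 genes at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2. That count was 3 without Ngn2ERT2 OHT 3 and 1 without DsRed no OHT 3.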

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

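The tests on the 3 libraries with oligodendrocyte transcripts and on cells without OHT were chosen after the results were seen, and the other tests in this part before.

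Regrouping cannot exclude chance for the counts of called genes, as 1 of 35 is the lowest share possible. For Ascl1ERT2 against DsRed cells with OHT, only 1 of the 35 splits of the 7 libraries, the real one, gave 2270 genes, and the highest other gave 868. For Ngn2ERT2 against DsRed cells it was 1 of 35 with 2119 genes, against 741 at most in the others. Between the factors it was 1 of 35 with 1069 genes, against 2.

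Ascl1ERT2 OHT 3, Ngn2ERT2 OHT 2 and DsRed OHT 4 held more oligodendrocyte-lineage RNA than the rest of their groups, by medians of 1.63, 2.72 and 2.19 (log2) over 14 genes of the list, which leaves out Olig1, Olig2 and Sox8. A response shared by the OHT libraries is argued against by the others, whose median difference from libraries without OHT was -0.14 (quartiles -0.33 and -0.04). Cells of the lineage may have been among the sorted cells. In 1 of the libraries, however, only 64.29% of the 14 genes lay above the rest of its group (85.71 and 71.43% in the others). Whether the sort passed only cells carrying the virus was not tested. A shared preparation also stays open, as deviations outside the oligodendrocyte and microglia lists correlated at 0.3639 or more, but a pair of other libraries reached 0.502 and no label names a preparation.

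Ngn2ERT2 cells differed from DsRed cells in 92 genes without OHT, and 90 of these had the same sign with OHT. A difference of virus stock or culture stays open, as cell make-up could shift the tested genes. Genes that rose with OHT in Ascl1ERT2 cells lay higher, by a median of 0.309 over 236 (quartiles -0.05 and 0.64). Those that fell, ependymal ones included, had -0.55 over 188, and all genes 0.02. The 236 and 188 genes had fry p-values of 0.0427 and 3.72e-06 from limma. Libraries that had received OHT despite their labels are argued against by a slope of 0.6077 (SE 0.036, 1000 resamples of genes) of the fold changes without OHT on those with OHT, where 0.9 or more was required. It covers the 424 genes called with OHT against none in Ascl1ERT2 cells, allows for error in the values with OHT, and was 0.536 to 0.680 without single libraries. Fusion protein activity without OHT may account for the difference. Between the factors, fold changes with and without OHT correlated at 0.6884 over 1069 called genes (0.4407 over all). A lasting culture difference would give this too.

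Of 242 tests of single libraries in groups of 4, 11 found a library far from the other 3, no more than the 1 of 20 or so that chance gives. In Ngn2ERT2 OHT cells these were Grpr (1.26 in library 4, a single read, 0 in the others), Sox8 (39.5 in library 3, others 80.24 to 91.92), Nqo1 (151.43 in library 1, others 75.12 to 84.37), Rorc (6.24 in library 3, others 10.54 to 11.65), Pcdh8 (194.14 in library 1, others 62.96 to 68.53) and Col1a1 (70.51 in library 4, others 110.01 to 111.23). In Ascl1ERT2 OHT cells they were Krt5 (13.86 in library 3, others 68.94 to 91.5), Gclc (40.43 in library 3, others 61.52 to 63.99), Stc1 (41.59 in library 3, others 68.73 to 75), Pgam2 (55.5 in library 2, others 23.11 to 24.88) and Lhx3 (65.76 in library 4, others 8.29 to 11.25).

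The response to OHT differed between Ascl1ERT2 and DsRed cells in 52 genes by limma's interaction test. Among named genes the differences (log2) were 3.912 for Cbfa2t3, 3.858 for Pkib, 2.727 for Sox11 and 4.062 for Flrt1, calls that no single library decided. They were 2.626 for Homer2, 3.806 for Cdkn1c, -2.514 for Cfap52, -1.929 for Cfap45, -1.459 for Fgfr3, 1.497 for Id1, 1.916 for Id2, -2.507 for Ccdc113 and -2.901 for Mak, 9 calls lost without Ascl1ERT2 no OHT 1 (adjusted p 0.0603 to 0.220) or DsRed no OHT 1 (0.0674 to 0.294). Homer2 was also lost without Ascl1ERT2 OHT 2 (0.0775), Ascl1ERT2 no OHT 3 (0.0604), DsRed no OHT 3 (with Cfap45, 0.0637 to 0.0691), DsRed OHT 2 (with Cfap52, 0.0871 to 0.0929), DsRed OHT 3 (with Cfap52, 0.0739 to 0.0950) and DsRed OHT 4 (with Id1, 0.0506 to 0.0567). Id1, Ccdc113 and Mak were also lost without the 3 libraries together (0.0526 to 0.0772), at 1.351, -2.501 and -2.639. Between Ascl1ERT2 and Ngn2ERT2 cells the response differed in 16 genes, with 2.901 for Pkib, 2.458 for Sox11, 1.473 for Id1, -1.978 for Ccdc153, 2.842 for Bmp7 and 2.072 for Ttll7. All 6 calls were lost without Ngn2ERT2 no OHT 3 (0.172 to 0.299) or Ngn2ERT2 no OHT 2 (0.0564 to 0.143), and 5 without Ascl1ERT2 no OHT 1 (0.0735 to 0.349), Ascl1ERT2 no OHT 3 (0.104 to 0.154), Ascl1ERT2 OHT 2 (0.0524 to 0.0791) or Ascl1ERT2 OHT 4 (0.0564). Those of Sox11, Id1, Ccdc153 and Ttll7 were lost without the 3 libraries (0.0563 to 0.0898), at 2.518, 1.434, -2.055 and 2.076.

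The library with conflicting labels lay above every DsRed library in Ascl1 (109.08, others 40.07 to 103.43), Neurod4 (3.76, others 0 to 3.04), Sox9 (1442.44, others 830.24 to 1350.68) and Olig2 (481.44, others 292.96 to 405.61).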

How the results depend on the processing

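Only leaving out 3 libraries together was chosen after the data were seen. Counts of called genes stayed within 1.5 times under pseudocount 0.5, a filter of 50, median-ratio and quantile rescaling in every comparison. Rescaling moved the median of all genes by at most 0.023 (log2). Where a count moved more, the cause was not tested, apart from fewer libraries or groups where these were left out.

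Leaving out each library in turn gave 1448 to 2213 genes for Ascl1ERT2 and 1055 to 2046 for Ngn2ERT2 against DsRed cells with OHT, 557 to 1043 for their overlap, and 693 to 1098 between the factors. For OHT against none it gave 93 to 436 in Ascl1ERT2, 0 to 4 in Ngn2ERT2 and 0 to 14 in DsRed cells, and without OHT 0 to 13 for Ascl1ERT2 and 3 to 61 for Ngn2ERT2 against DsRed. Differences between OHT responses gave 9 to 68 (Ascl1ERT2 and DsRed), 0 to 3 (Ngn2ERT2 and DsRed) and 3 to 20 (Ascl1ERT2 and Ngn2ERT2).

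OHT against none in Ascl1ERT2 cells (424) had 158 with only the compared groups in the model and 704 with DESeq2. OHT against none in Ngn2ERT2 cells (2) had 25 with DESeq2, 7 with the conflicting library placed by its title, 5 by its tag and 4 without the 3 libraries. Ascl1ERT2 against DsRed cells without OHT (1) had 0 in limma without trend and robust, 0 with only the compared groups, 2 with edgeR, 21 with DESeq2 and 2 without the 3 libraries. Ngn2ERT2 against DsRed cells without OHT (92) had 55 without a filter, 48 without trend and robust, 0 with only the compared groups (limma, 4 libraries), 353 by the title, 286 with DESeq2 and 206 without the 3 libraries. The difference between OHT responses of Ascl1ERT2 and DsRed cells (52) had 29 without trend and robust, 117 by the title and 155 with DESeq2, and that of Ascl1ERT2 and Ngn2ERT2 cells (16) had 7 with only the compared groups and 62 with DESeq2. That of Ngn2ERT2 and DsRed cells (0 by limma) had 1 without a filter, with a pseudocount of 5, by the title and by the tag, and 2 with DESeq2.

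Pairing by replicate number is unclear: 4 of 27 such pairs correlated above 0.1 (up to 0.5015). Of 17 libraries 2 correlated best with their own number. With the replicate block the counts were 1608 and 1299 against DsRed cells with OHT, 642 shared, 624 between the factors, 111, 1 and 0 for OHT against none in Ascl1ERT2, Ngn2ERT2 and DsRed cells, 0 and 7 without OHT, and 21, 0 and 1 for the differences of response. It changed no other count by over 1.5 times.

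Of 52 camera results, an estimated correlation ended 50 and fry 29, the block ended 9, and leaving out single libraries ended 19 and reversed 3. Leaving out the 3 libraries together ended 10 and reversed 2, and median-ratio rescaling ended 0. The reversed ones were microglia genes in Ascl1ERT2 against DsRed cells with OHT (adjusted p = 0.7374 without DsRed OHT 4), and with OHT against none in DsRed cells microglia genes (0.0192 without DsRed OHT 4, 0.00102 without the 3 libraries) and the interferon response (0.9891 and 0.991). Of 287 results for named genes, leaving out single libraries ended 111, the block 70, leaving out the 3 libraries 36 and a pseudocount of 5 ended 3, with the same direction. A filter of 50 ended 5 of 241. Isoforms as separate features were not run, since the table lists genes.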

Other observations

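All tests in this part were chosen after the main results were seen. Lists came from general knowledge, without genes already examined.

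Genes of motile cilia beyond the ependymal list were lower with both factors. Of 25 tested, 16 fell in Ascl1ERT2 and 14 in Ngn2ERT2 cells against DsRed cells with OHT, and none rose. Among them Lrriq1 had log2 fold changes of -2.35 ± 0.29 and -1.20 ± 0.29 (SE) with Ascl1ERT2 and Ngn2ERT2, Ccdc40, which anchors dynein arms, -1.74 ± 0.24 with Ascl1ERT2, and Zmynd10, a dynein assembly factor, -1.61 ± 0.27 with Ngn2ERT2. Medians were -1.25 and -0.88. A wider fall of motile cilia genes, or of cells that carry them, may therefore accompany both factors (fry adjusted p = 9.03e-06 and 1e-04, over 12 tests, and camera p = 0.00112 and 0.00597 with an estimated correlation). With OHT against none, 7 fell in Ascl1ERT2 cells (fry adjusted p = 1.14e-04), and limma called 0 in Ngn2ERT2 and DsRed cells (fry adjusted p = 0.133 and 0.740).

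Targets of the coactivator YAP were examined because Ccn2 and Thbs1 fell with both factors. Of 18 tested, 6 fell in Ascl1ERT2 cells, and 6 fell and 2 rose in Ngn2ERT2 cells, against DsRed cells with OHT. The coagulation factor gene F3 had -2.34 ± 0.30 and -2.29 ± 0.30 and Dock5, a regulator of cell spreading, -1.42 ± 0.28 and -1.37 ± 0.28. Lower output of YAP targets may accompany both factors (fry adjusted p = 0.00405 and 0.035, medians -0.57 and -0.28), but camera with an estimated correlation gave p = 0.0644 and 0.177, so the list is not shown to differ from other genes. With OHT against none limma called 0 of the 18 in Ascl1ERT2, Ngn2ERT2 and DsRed cells (fry adjusted p = 0.325, 0.773 and 0.377).

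OHT responses in Ascl1ERT2 and Ngn2ERT2 cells correlated at 0.318 over 15293 genes and 0.551 over the 424 called in Ascl1ERT2 cells. The sign was the same for 341. Effects of OHT itself or the 3 libraries were not tested.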
